A study of Homo sapiens with 8 samples.

How the data were processed

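OCI-AML3 is an established human acute myeloid leukaemia line that carries a mutated NPM1 gene, whose protein leaves the nucleolus for the cytoplasm. Total RNA from these cells was hybridised to 8 Agilent gene expression arrays in 3 groups. Per the labels, 3 arrays held cells with a control short hairpin RNA (shRNA) and no doxycycline, 2 held cells with an ATG5 shRNA and 3 held cells with an NPM1 shRNA. Both hairpin groups received 1 µg/ml doxycycline for 6 days, which switches an inducible hairpin on. The comparisons against control therefore combine the hairpin with doxycycline, and only the comparison of the hairpin groups with each other holds doxycycline constant. The series' design text calls the replicates biological but does not say that they came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

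Per the file headers, the deposited intensity values of each spot were made with Agilent Feature Extraction 10.7.3.1 from 1 scanned channel, on 1 slide with 2 rows of arrays, and probe positions refer to the hg19 build. The labels name the dye Cy5 while the files name the channel green. With 1 channel this changes no direction. Each array had 62976 spots, of which 58717 were not controls, and 42405 probes. The authors' deposited value table holds log2 values, as set against the scanner values of each array. Every column had a median of 5.06 to 3 significant digits, a floor at 3.32 and a maximum of 17.2. Across probes, each column correlated with its own array at r from 0.9986 to 0.9997. The scale and direction of that table were therefore settled, while its normalization method stays unknown. Centring alone is unlikely, since the maximum as well as the median was equal across columns. The table may therefore not be separate from quantile normalization, which is among the alternatives below. Agilent Feature Extraction is also named in the submitters' processing notes, with no version.

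The background-subtracted processed intensity was put on the log2 scale, and the 75th percentile of the array's non-control spots was subtracted. All levels below are on this scale. Spots marked as outliers were dropped, spots of a probe were averaged, and 57 probes with no usable spot on some array were left out. A further 136 probes for Y-linked genes and XIST were left out. The 26098 probes marked well above background on all arrays of at least 1 group were kept. For each gene the probe with the highest mean over the 8 arrays was used, which gave 21488 genes. The 13883 of them with an approved symbol could be named. Probes were named through the RefSeq accession in the files for 25419 probes, through another listed accession for 180, a current symbol for 1042, a gene number for 416 and an older symbol for 345. The other 15003 kept the name in the file. The reference table (GRCh38.p14) served for names only, so exons and untranslated regions were not assigned to probes.

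Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 8 arrays, with 1 pooled variance per gene, 5 residual degrees of freedom and 1.94 prior degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. All tests were two-sided. Errors of differences are limma's standard errors (SE), and errors of levels are standard deviations (SD). An exact permutation test could not go below p = 0.1 with 3 against 3 arrays, or below 0.2 with 2 against 3. A probe not well above background on any array of a group has only a bound there. Its difference is then given as "at least N-fold", from the brighter group's mean against the lowest signal that was well above background on each array of the dimmer group, or the probe's own signal where that was higher. Counts of genes by fold used all signals raised in this way.

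The lists were fixed before the data were examined, as were the comparisons, the tests and the rule for naming genes. The 26 lists covered HOX and MEIS genes, core autophagy machinery, lysosome, monocyte and macrophage differentiation, neutrophil granules, stem and progenitor cells, p53 targets, ribosome biogenesis, cytosolic ribosomal proteins, G2/M and mitosis, S phase and DNA replication. They also covered ATF4 and amino acid stress, the unfolded protein response, genes of mitochondrial DNA, nuclear oxidative phosphorylation, glycolysis and hypoxia, cholesterol synthesis, NRF2 targets, interferon response, NF-kB and inflammatory cytokines, apoptosis regulators, replication-dependent histones, immediate early and heat shock genes, and markers of erythroid and megakaryocyte, lymphoid, and fibroblast or epithelial cells. Each list was tested against all other genes with camera in limma, at a preset inter-gene correlation of 0.01 and again with an estimated correlation, with adjustment over the 26 lists of a comparison. In other splits of the control and NPM1 arrays, which mix the groups, the preset correlation still called 3 to 6 lists each. Such a call alone is therefore weak. The rule named 13 genes in every comparison, the 8 called genes with the largest rise and the 8 with the largest fall against control (5 and 5 between the hairpins) whose groups did not overlap, and up to 4 called members of each list. The other probes of a gene never gave a called change in the opposite direction to the one used, among the genes named.

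The procedures were tested on simulated data with 200 changed genes among 21488. For a true difference of 1 on the log2 scale, 34.3% of changed genes were recovered for NPM1 shRNA against control, 35.8% for ATG5 shRNA against control and 34.3% between the hairpins. For a difference of 2 the shares were 74.2%, 66.7% and 68.2%, and for 0.5 they were 7.46%, 1.49% and 1.49%. Among unchanged genes 7, 5 and 4 were called, in the same order. Every simulated array had the pooled spread of the gene. In the real arrays the median SD of a gene was 0.25 in the control, 0.13 in the ATG5 and 0.09 in the NPM1 group. These shares may therefore not hold for each comparison. Alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, no filter on dim probes, the mean of a gene's probes, the replicate number as a block, only the 2 groups compared, a variance trend with robust estimation, array weights, the authors' table, and leaving out each array. A term for the row on the slide was added after the data were seen. The comparisons that share control arrays were simulated 100 times without any effect. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

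Some genes that the lists and counts include are not reported here by name.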

Results

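Gene expression was measured on 8 one-colour arrays of OCI-AML3 leukaemia cells. There were 3 control shRNA arrays, 2 ATG5 shRNA arrays and 3 NPM1 shRNA arrays. Signal strength differed between arrays. The 75th percentile of the processed signal ran from 372 on ATG5 replicate 2 to 1032 on control replicate 3, and 60.1% to 69.9% of spots were well above background on the same arrays. No spot was saturated, and the 75th percentile stood 19.8 to 50.5 times above the local background. Replicates correlated across genes at r from 0.994 to 0.996 in the NPM1 group, 0.978 to 0.987 in the control group and 0.983 between the ATG5 arrays, and the median SD of a gene in these groups was 0.09, 0.25 and 0.13 on the log2 scale. Genes are not independent replicates in these correlations. The number of arrays limits the precision of every value below. Control arrays and ATG5 replicate 1 lay in slide row 1, and ATG5 replicate 2 and the NPM1 arrays in slide row 2.

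NPM1, a nucleolar chaperone of ribosome assembly, was lower in the NPM1 shRNA arrays, at 5.03 ± 0.07 (SD, n = 3) against 6.60 ± 0.52 (SD, n = 3) in the control arrays. The difference was -1.57 (SE 0.28, adjusted p = 0.00794 by limma), a 2.97-fold fall, for the probe at chromosome 5, 170837789 to 170837848 (hg19), with the sequence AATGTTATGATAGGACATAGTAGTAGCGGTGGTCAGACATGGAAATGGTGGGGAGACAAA. A second NPM1 probe read 3.57 ± 0.01 against 5.74 ± 0.25 and a further one 2.27 ± 0.01 against 4.33 ± 0.32 in the same arrays. ATG5, which is joined to ATG12 to build the complex that lipidates LC3 proteins, read 0.79 ± 0.14 (SD, n = 2) in the ATG5 shRNA arrays and 1.38 ± 0.15 (SD, n = 3) in the control arrays. This difference of -0.59 (SE 0.12) did not pass the test (adjusted p = 0.0601). Its probe lies at chromosome 6, 106633866 to 106633925 (hg19), with the sequence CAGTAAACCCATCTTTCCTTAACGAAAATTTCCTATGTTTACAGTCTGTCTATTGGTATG. A dimmer ATG5 probe read -4.19 ± 1.40 against -2.59 ± 0.18. Each hairpin group had the lowest level of its own target: NPM1 differed by 0.38 between ATG5 shRNA and control arrays (SE 0.32, adjusted p = 0.537), and ATG5 was 0.41 higher in NPM1 shRNA than in control arrays (SE 0.11, adjusted p = 0.0399). The last call was lost without control replicate 2 (adjusted p = 0.073) and without NPM1 replicate 1 (0.14), 2 (0.136) or 3 (0.0913). The ATG5 fall was called without control replicate 1 (-0.67, adjusted p = 0.0182) and with a variance trend and robust estimation (0.0285), and its adjusted p ran from 0.0182 to 0.32 over the alternatives. With a term for the slide row, which was added after the data were seen, the NPM1 difference was -2.25 and no longer called (adjusted p = 0.0605).

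**Figure D1:**
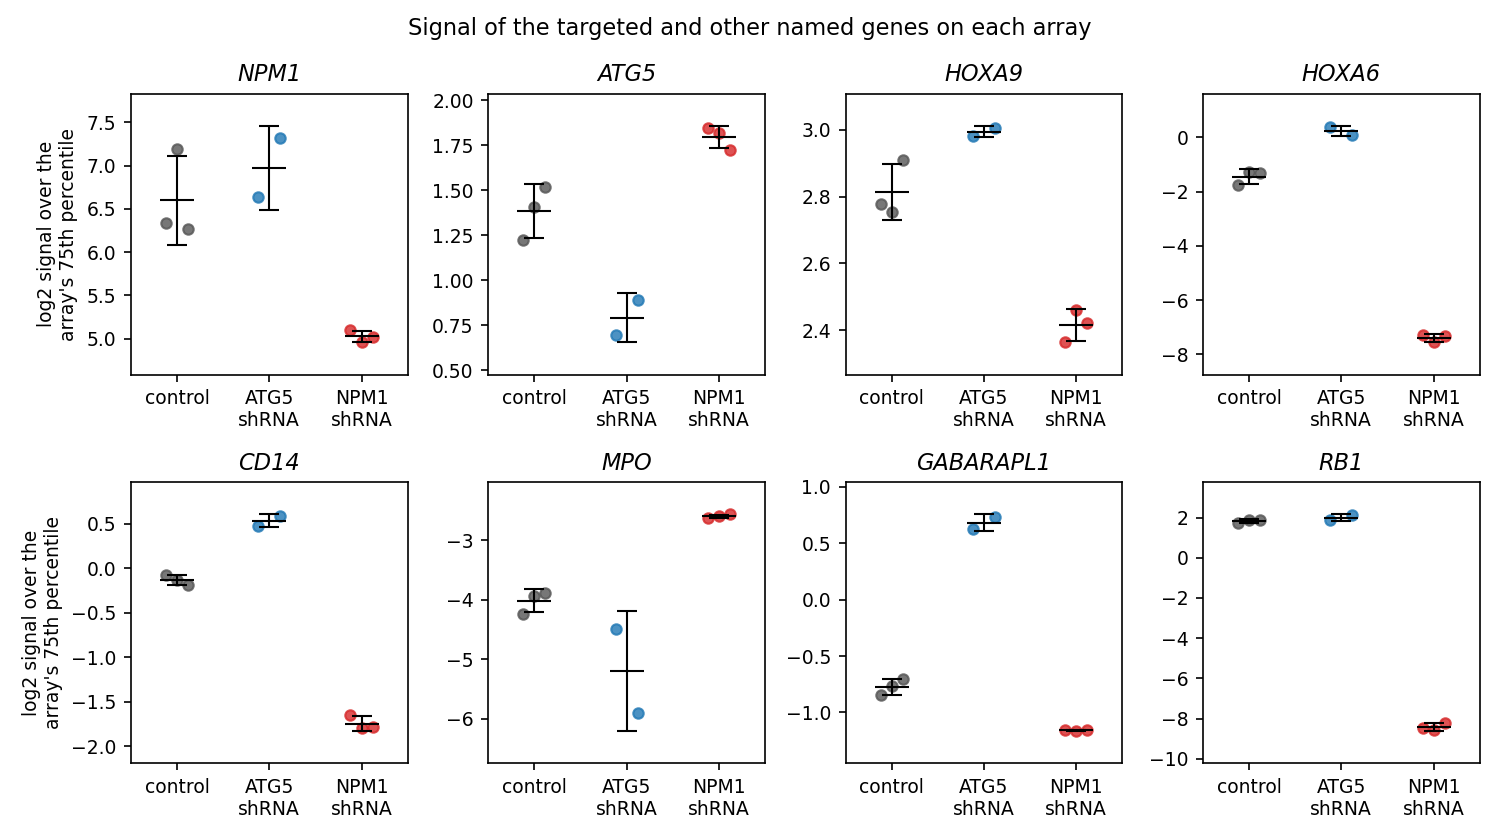
Each point is the log2 signal of 1 array relative to its 75th percentile, and lines show the mean ± SD of the 3 control, 2 ATG5 shRNA and 3 NPM1 shRNA arrays for 8 genes. NPM1 was lowest in the NPM1 shRNA arrays (5.03), ATG5 was lowest in the ATG5 shRNA arrays (0.79, not called), and RB1 was not well above background on any NPM1 shRNA array.

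The first comparison asked what an NPM1 shRNA with doxycycline changed against the control shRNA without it. RB1, the retinoblastoma cell cycle repressor, was at least 272-fold lower in the NPM1 shRNA arrays, where it was not well above background on any of 3 arrays (adjusted p = 3.35e-07). RCBTB2, its neighbour on chromosome 13, was at least 130-fold lower, the surface receptor CD93 at least 90.7-fold, CEP15 at least 56.4-fold, the prostaglandin receptor PTGER3 at least 49.2-fold, the homeobox factor LHX1 at least 40.8-fold and the keratin KRT23 at least 29.7-fold. ANKRD2 differed by -7.05 (SE 0.23, adjusted p = 3.49e-06) and was well above background on 1 of 3 NPM1 arrays. In the other direction, MEGF6 was at least 43.3-fold higher, BRINP3 at least 19.4-fold and FOXL2NB at least 8.73-fold. DNAI3 rose by 6.05 (SE 0.20, adjusted p = 3.32e-06), the developmental regulator DACH1 by 5.10, the protease inhibitor SERPINB2 by 4.56 (SE 0.12, adjusted p = 1.65e-06) and the secreted glycoprotein CHI3L1 by 4.23 (SE 0.22, adjusted p = 2.37e-05). limma called 4757 of 21488 genes, 2065 higher and 2692 lower, and 1733 of them differed at least 2-fold with dim signals at their bound (496 higher, 1237 lower). The groups did not overlap for 44.2% of genes, where chance gives 10%. Of the calls 43.4% were higher, against 54.9% with quantile normalization, 73.3% with median centring and 58.2% in the authors' table. The median of all genes was -0.10, and 0.01, 0.23 and 0.02 with those scalings. The count was 2885, 2861 or 3002 without NPM1 replicate 1, 2 or 3 and 3040 with normexp. With a term for the slide row it was 1525, and 59 of the 114 named calls were lost. All control arrays lay in row 1 and all NPM1 arrays in row 2, so this term rests on the difference between the 2 ATG5 arrays. Whichever array was left out, 2659 genes kept their call and direction.

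Of the HOX and MEIS genes, transcription factors held high in NPM1-mutated leukaemia, more were called lower than higher in the NPM1 shRNA arrays. HOXA6 was at least 28.2-fold lower, HOXA3 at least 19.0-fold and HOXB8 at least 15.8-fold, and HOXA5 differed by -3.97 (SE 0.24, adjusted p = 4.03e-05) and was well above background on 1 of 3 NPM1 arrays. HOXA10 fell by 0.81 (SE 0.15, adjusted p = 0.00793), HOXA9 by 0.40 (SE 0.09, adjusted p = 0.0178) and MEIS1, a HOXA9 cofactor, by 0.43 (SE 0.08, adjusted p = 0.0112), while PBX3, a further cofactor, differed by -0.07 (adjusted p = 0.738). Of 21 measured members 13 were lower and 2 higher (15 and 3 when adjusted over the list alone), with camera adjusted p = 0.000108, and adjusted p = 0.129 with an estimated correlation. HOXA2, HOXA4, HOXA11 and HOXA13 were looked at after the values were seen: HOXA2 was at least 3.13-fold and HOXA4 at least 2.14-fold lower, HOXA11 fell by 0.73 and HOXA13 by 0.93. The higher members, MEIS2 at 1.72 and HOXB5 at 0.86, were also looked at then, as was HOXC4, which is on no list and rose by 3.01 (SE 0.09, adjusted p = 2.15e-06). HOXB8 was at least 10.5-fold lower without control replicate 1. The HOXA9 call was lost without NPM1 replicate 1 (adjusted p = 0.0892), 2 (0.0653) or 3 (0.0719), and the MEIS1 call without the same arrays (0.0549, 0.0594 and 0.0552). Both calls and that of HOXA10 were also lost with median centring.

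**Figure D2:**
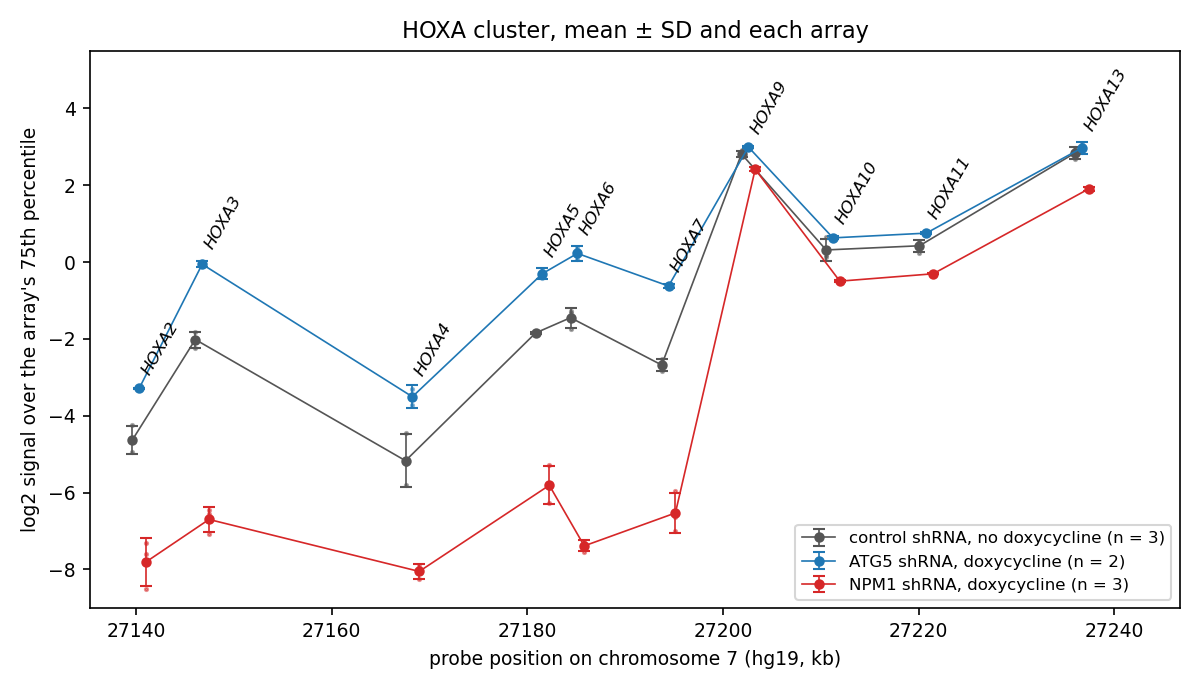
Mean log2 signal relative to the 75th percentile (large points; error bars, SD; small points, each of the 3 control, 2 ATG5 shRNA and 3 NPM1 shRNA arrays) is drawn against the probe position of each HOXA gene on chromosome 7 (hg19, kb), with the groups shifted sideways to keep them apart. HOXA6 reads -7.39 in NPM1 shRNA, -1.45 in control and 0.22 in ATG5 shRNA arrays, while HOXA9 reads 2.42, 2.81 and 3.00.

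Monocyte genes moved both ways. CD14, a co-receptor for lipopolysaccharide, fell by 1.61 (SE 0.09, adjusted p = 3.06e-05), the lectin FCN1 by 3.05 and the chemokine receptor CX3CR1 by 1.97, while the integrins ITGAX and ITGAM rose by 1.98 and 1.23 (adjusted p = 0.00052 and 0.000586). Of 25 measured monocyte and macrophage genes 11 were lower and 5 higher (14 and 5 adjusted over the list alone), and the list did not differ from other genes (camera adjusted p = 0.185). Among 16 neutrophil genes 5 were higher and 5 lower (7 and 5 adjusted over the list alone; camera adjusted p = 0.523). The antimicrobial peptide CAMP rose by 2.95 and the granule enzyme MPO by 1.42 (SE 0.33, adjusted p = 0.0226), while the adhesion molecule CEACAM1 fell by 1.68. Of 11 stem and progenitor genes 4 were lower and 1 higher (6 and 1 adjusted over the list alone; camera adjusted p = 0.173). The interleukin 3 receptor chain IL3RA fell by 1.42, SOX4 by 1.13 and the adhesion receptor CD44 by 1.03, and the receptor kinase FLT3 rose by 0.74. The MPO call was lost without control replicate 1 (adjusted p = 0.0546) or 2 (0.0517) and without NPM1 replicate 1 (0.0716), 2 (0.0738) or 3 (0.0733).

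In the glycolysis and hypoxia list all called genes were lower in the NPM1 shRNA arrays. The hypoxia-induced peptide ADM was at least 17.4-fold lower, and the glycolytic enzymes ENO2 and ALDOC fell by 2.41 (SE 0.27, adjusted p = 0.000879) and 2.05 (SE 0.11, adjusted p = 2.15e-05) and the hypoxia target ANKRD37 by 1.45. Of 32 measured members 17 fell and none rose (17 and 0 adjusted over the list alone; camera adjusted p = 2.44e-05, and adjusted p = 0.0481 with an estimated correlation). Cholesterol synthesis genes were lower for 14 of 24 members and higher for 1 (15 and 1 adjusted over the list alone; camera adjusted p = 9.09e-05, and adjusted p = 0.129 with an estimated correlation), with the sterol isomerase EBP at -2.15 (SE 0.15) and TM7SF2 at -1.09. Nuclear genes of oxidative phosphorylation were higher for 7 of 38 and lower for none (7 and 0 adjusted over the list alone; camera adjusted p = 3.58e-05, and adjusted p = 0.315 with an estimated correlation), led by the complex III subunit UQCRC1 at 0.67 and the cytochrome oxidase subunit COX7B at 0.52. Of 12 genes of mitochondrial DNA, ND1 of complex I alone was called (1 lower and 0 higher, none adjusted over the list alone; -1.02, camera adjusted p = 0.219). The UQCRC1 call was lost without NPM1 replicate 3 (adjusted p = 0.0554), and the ND1 call without control replicate 2 (0.0526) or NPM1 replicate 1 (0.0821), 2 (0.104) or 3 (0.0808). The list of mitochondrial DNA had a positive median of 0.24, opposite to ND1. It was called without control replicate 1 (0.0139), at a median of 0.61 relative to all genes.

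Lysosomal genes rose for 13 of 40 measured members and fell for 3 (17 and 3 adjusted over the list alone), with the lysosomal membrane protein SCARB2 at 0.98 (SE 0.09, adjusted p = 0.00027), the galactosidase GLA at 0.79 (SE 0.13, adjusted p = 0.00628) and the protease CTSH at -0.85 (SE 0.14, adjusted p = 0.0055). The list differed from other genes (camera adjusted p = 9.09e-05), also with an estimated correlation (adjusted p = 0.0481). SQSTM1, the selective autophagy receptor also called p62, rose by 0.58 (SE 0.09, adjusted p = 0.00395), as did the LC3 protease ATG4D by 0.58, while MAP1LC3B, the common LC3 protein, differed by 0.31 (SE 0.10, adjusted p = 0.0591). Of 38 genes of the core autophagy machinery 6 were higher and 3 lower (8 and 4 adjusted over the list alone; camera adjusted p = 0.0931). NRF2 targets, which counter oxidative stress, were higher for 8 of 22 and lower for 2 (9 and 3 adjusted over the list alone; camera adjusted p = 0.00292, and adjusted p = 0.129 with an estimated correlation), among them PGD (0.94) of the pentose phosphate pathway and the cystine transporter SLC7A11 (0.82). Without a filter on dim probes the autophagy list was called (adjusted p = 0.0151), as it was with median centring (0.0226), with the mean of a gene's probes (0.0343) and without control replicate 3 (0.0415). The CTSH call was lost with median centring and the ATG4D call with normexp.

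Regulators of cell death changed in both directions. The pro-apoptotic BIK rose by 2.99 (SE 0.11, adjusted p = 4.67e-06) and BMF by 2.11, the death receptor TNFRSF10A by 1.15 and the anti-apoptotic BCL2 by 1.36 (SE 0.09, adjusted p = 7.93e-05). Of 28 apoptosis regulators 6 were higher and 4 lower (6 and 6 adjusted over the list alone; camera adjusted p = 0.316). Of 30 p53 targets 7 were higher and 1 lower (8 and 3 adjusted over the list alone; camera adjusted p = 0.167). Among those, EDA2R rose by 3.46, PMAIP1 by 1.03 and GDF15 by 0.94, SPATA18 was at least 1.85-fold lower, and the cell cycle inhibitor CDKN1A differed by 0.42 (SE 0.20, adjusted p = 0.186). Interferon response genes were higher for 10 of 32 and lower for 6 (11 and 6 adjusted over the list alone; camera adjusted p = 0.081), with IFI27 at 3.95, IFI44 at 2.76 and HERC5 at 2.07. NF-kB and cytokine genes were lower for 10 of 25 and higher for 6 (10 and 6 adjusted over the list alone; camera adjusted p = 0.749). CD40 fell by 1.46, CXCL1 by 1.03 and CXCL2 by 0.99, and CCL20 was at least 1.75-fold higher. The p53, interferon and apoptosis lists had medians of -0.02, -0.03 and -0.07 and means of 0.11, 0.34 and 0.20, with camera pointing up. The interferon list was called without control replicate 3 (adjusted p = 0.0403), ATG5 replicate 1 (0.0424) or ATG5 replicate 2 (0.0424), and in 4 of the other alternatives. The p53 list was called without a filter on dim probes (0.0405). The calls of CCL20 and SPATA18, both near background, were lost with normexp.

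Of the growth and stress lists, camera called replication-dependent histones alone. MYC, a driver of ribosome synthesis, fell by 0.53 (SE 0.13, adjusted p = 0.0264), and the serine synthesis enzyme PHGDH, the lipoprotein receptor VLDLR, the mTORC1 inhibitor DDIT4 and the cysteine synthesis enzyme CTH fell by 1.49, 1.60, 1.33 and 1.11. The ATF4 and amino acid stress list held 6 lower and 4 higher genes of 34 (6 and 5 adjusted over the list alone; camera adjusted p = 0.941), and the unfolded protein response 2 lower, among them the transcription factor XBP1 (-0.61), and 1 higher of 21 (1 and 1; 0.209). Ribosome biogenesis held 1 lower of 38 (0 adjusted over the list alone; 0.941), cytosolic ribosomal proteins 1 lower of 44 (0; 0.167), and G2/M and mitosis 1 higher of 34 (0; 0.347). S phase held 5 lower and 1 higher of 40 (4 and 1; 0.479), with the origin licensing factor CDT1 at -0.49 and cyclin E1 (CCNE1) at 0.55. Replication-dependent histones had a median of -0.50 (-0.40 relative to all genes) and were lower for 3 of 35 (0 adjusted over the list alone; camera adjusted p = 0.00213, and adjusted p = 0.698 with an estimated correlation), and the call was lost with the slide row term (0.852). Immediate early and heat shock genes were lower for 5 and higher for 3 of 25 (5 and 4; 0.941), with the heat shock gene HSPA6 at -1.75 and JUN at 1.00. Ribosome biogenesis had a median of -0.06 and a mean of -0.01, and the immediate early list -0.09 and -0.16, with camera pointing up in both. The MYC call was lost without control replicate 2 (adjusted p = 0.0506) or 3 (0.0579) and without NPM1 replicate 1 (0.0964), 2 (0.0838) or 3 (0.0897), and the calls of MYC, CDT1 and XBP1 with median centring. Ribosomal proteins were called as a list without control replicate 3 (adjusted p = 0.00517), with normexp (0.0126) and with the slide row term (0.0257).

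Markers of other cell types were called in both directions in the NPM1 shRNA arrays. The haemoglobin chain HBB fell by 3.78 (SE 0.29, adjusted p = 0.000131) and HBA2 by 2.37, HBD was at least 5.36-fold and the platelet chemokine PPBP at least 1.54-fold lower. Of 19 erythroid and megakaryocyte markers 7 were lower and 1 higher (10 and 1 adjusted over the list alone; camera adjusted p = 0.00152, and adjusted p = 0.315 with an estimated correlation). The B cell factor EBF1 fell by 2.70 (SE 0.11, adjusted p = 7.83e-06) and the adhesion molecule NCAM1 rose by 0.77, among 3 lower and 1 higher of 13 lymphoid markers (3 and 1 adjusted over the list alone; camera adjusted p = 0.941). The collagen chain COL1A2 was at least 6.74-fold lower, COL6A1 fell by 1.71 and fibronectin (FN1), well above background on 1 of 3 NPM1 arrays, by 1.68, among 5 lower and 1 higher of 10 fibroblast and epithelial markers (5 and 1 adjusted over the list alone; camera adjusted p = 0.164). The PPBP and FN1 calls were lost with normexp, and the fibroblast list was called without a filter on dim probes (0.0405).

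**Figure D3:**
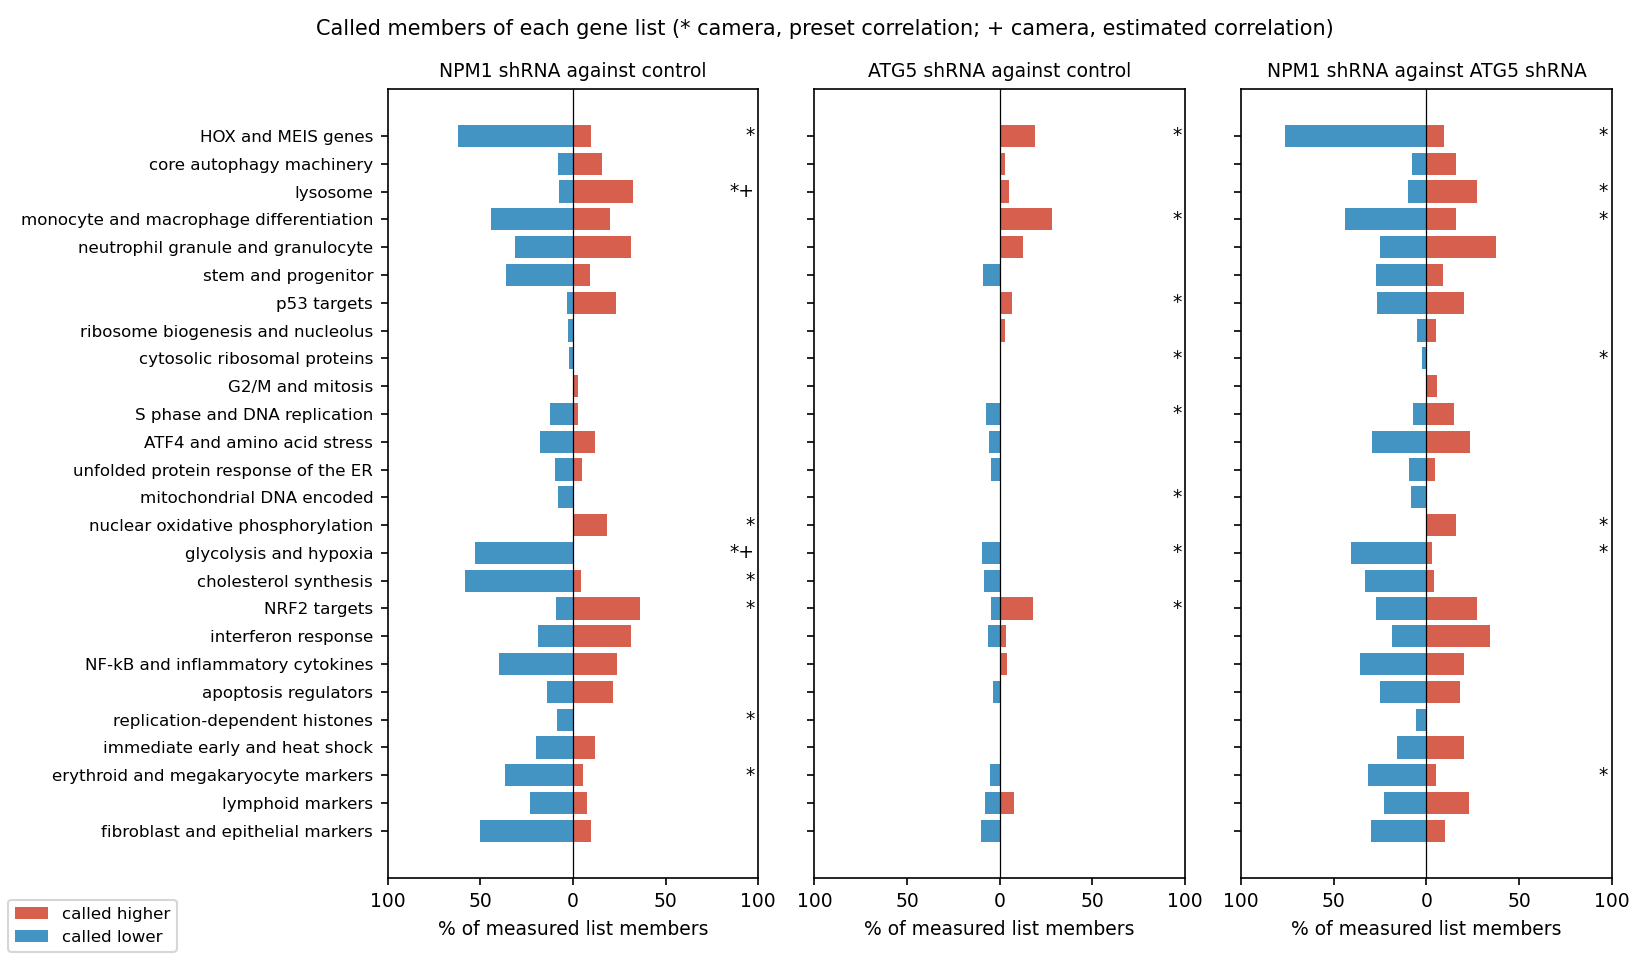
Bars give the percentage of measured members of each of the 26 lists that were called higher or lower in the 3 comparisons, with a star for a camera call at the preset correlation and a plus sign at an estimated one. Glycolysis and lysosome lists carry both marks in NPM1 shRNA against control.

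The second comparison asked what an ATG5 shRNA with doxycycline changed against the control. The collagen crosslinking enzyme LOX rose by 3.06 (SE 0.16, adjusted p = 0.002), the growth factor binding protein IGFBP5 by 2.46 (SE 0.11, adjusted p = 0.002), CD163, a macrophage scavenger receptor, by 2.14 (SE 0.14, adjusted p = 0.00268). The ganglioside enzyme B4GALNT1 and CRYBG1 rose by 2.12 and 2.08. PRR16 was at least 3.50-fold higher, and STYK1 and HOXA7 rose by 2.17 and 2.06. The serpin SERPINB10 fell by 2.57 (SE 0.20, adjusted p = 0.00369), RGCC by 1.82 (SE 0.15), COL1A2 by 1.79 and MTARC1 by 1.70, and the relaxin receptor RXFP1 was at least 3.19-fold, GARIN1A at least 1.56-fold, MATN2 at least 1.54-fold and KSR1 at least 1.13-fold lower. limma called 615 genes, 355 higher and 260 lower, of which 179 differed at least 2-fold with dim signals at their bound (125 higher, 54 lower). LOX, STYK1 and FCGR3A were well above background on 1 of 3 control arrays and COL1A2 on 1 of 2 ATG5 arrays. The groups did not overlap for 32.9% of genes, where chance gives 20%. With only the ATG5 and control arrays in the fit limma called 0 genes (2658 at an unadjusted p under 0.05), so the calls depend on a fit that includes the NPM1 arrays. The median SD of a gene was 0.09 in NPM1 and 0.25 in control arrays, so the pooled spread may be too small for this comparison. Of the calls 57.7% were higher, against 71.8% with normexp, 75.1% with median centring and 34.2% without ATG5 replicate 1. The median of all genes was 0.02, and 0.20 with normexp. The count was 517 or 44 without ATG5 replicate 1 or 2, where the lone ATG5 array is assumed to vary like the other groups, and 3239, 275 or 203 without control replicate 1, 2 or 3 and 122, 119 or 151 without NPM1 replicate 1, 2 or 3. It was also 252 with normexp, 173 with median centring and 91 without a filter. A slide row term here leaves ATG5 replicate 1 alone against the control arrays, so it is the same fit as leaving out ATG5 replicate 2. Whichever array was left out, 35 genes kept their call, among them LOX, IGFBP5, CD163, B4GALNT1, CRYBG1, SERPINB10, RGCC, GABARAPL1, CAMP and CCL2. The other 46 of the 56 named calls were lost without at least 1 array. Without ATG5 replicate 2, PRR16, STYK1, HOXA7, COL1A2, RXFP1, GARIN1A, MATN2 and KSR1 lost their calls (adjusted p from 0.0622 to 0.189). Some of these genes or MTARC1 also lost theirs without ATG5 replicate 1 (0.0615 to 0.101), control replicate 2 (0.0502 to 0.072) or 3 (0.0559 to 0.0949), or NPM1 replicate 1 (0.0583 to 0.0777), 2 (0.0548 to 0.08) or 3 (0.05 to 0.0698). With normexp GARIN1A, KSR1 and MATN2 turned to 0.16, 0.36 and 0.29.

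In the HOX and monocyte lists all called genes were higher in the ATG5 shRNA arrays, and most members were not called. HOXA3 rose by 1.96 (SE 0.21, adjusted p = 0.00977), HOXA6 by 1.67 and HOXA5 by 1.55, while HOXA9, HOXA10, MEIS1 and PBX3 differed by 0.18, 0.31, 0.16 and 0.44 (adjusted p = 0.339, 0.324, 0.37 and 0.146). Of 21 HOX and MEIS genes 4 were higher and 0 lower (9 and 0 adjusted over the list alone; camera adjusted p = 8.9e-06, and adjusted p = 0.0709 with an estimated correlation). The Fc receptor FCGR3A rose by 1.85 (SE 0.20, adjusted p = 0.00968), FCN1 by 1.21, ITGAM by 0.78 (adjusted p = 0.0413) and CD14 by 0.67 (SE 0.10, adjusted p = 0.0268). Of 25 monocyte and macrophage genes 7 were higher and 0 lower (10 and 0 adjusted over the list alone; camera adjusted p = 9.57e-05, and adjusted p = 0.0709 with an estimated correlation). CAMP rose by 1.78 and CEACAM1 by 1.19, MPO differed by -1.18 (adjusted p = 0.134), and 2 of 16 neutrophil genes were higher and 0 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.772). FLT3 fell by 0.77, the 1 call among 11 stem and progenitor genes (2 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.361). Without ATG5 replicate 2 all of these gene calls but that of CAMP were lost (adjusted p from 0.0553 to 0.24). The CD14 and ITGAM calls, and some of HOXA5, FCN1 and FLT3, were also lost without ATG5 replicate 1 (0.0606 to 0.108), control replicate 2 (0.0563 to 0.0794) or 3 (0.064 to 0.109), or NPM1 replicate 1 (0.0777 to 0.111), 2 (0.08 to 0.107) or 3 (0.0635 to 0.0991).

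GABARAPL1, a member of the LC3 family that ATG5 helps to lipidate, rose by 1.45 (SE 0.10, adjusted p = 0.00268), the 1 call among 38 genes of the core autophagy machinery (1 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.772). SQSTM1 and MAP1LC3B differed by 0.27 and -0.04 (adjusted p = 0.181 and 0.848). The lysosomal enzymes FUCA1 and CTSD rose by 1.52 (SE 0.13, adjusted p = 0.00453) and 0.90, the calls among 40 lysosomal genes (2 and 0 adjusted over the list alone; camera adjusted p = 0.323). NRF2 targets were higher for 4 of 22 and lower for 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.00152, and adjusted p = 0.0918 with an estimated correlation). The malic enzyme ME1 rose by 1.32, the haem oxygenase HMOX1 by 1.22 and NQO1 by 0.97, and AKR1C1 fell by 1.37. Of 30 p53 targets EDA2R and TIGAR rose, by 1.05 and 0.85 (13 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.000601, and adjusted p = 0.0709 with an estimated correlation), with CDKN1A at 0.12 (adjusted p = 0.808). The p53 list was not called with normexp (adjusted p = 0.0575). Without ATG5 replicate 2 all of these gene calls but that of GABARAPL1 were lost (adjusted p from 0.05 to 0.236). Some of CTSD, TIGAR, HMOX1 and NQO1 also lost theirs without ATG5 replicate 1 (0.0796 to 0.101), control replicate 2 (0.0702 to 0.0914) or 3 (0.0522 to 0.0949), or NPM1 replicate 1 (0.0683 to 0.107), 2 (0.0667 to 0.0969) or 3 (0.0594 to 0.0904).

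Glycolysis and hypoxia genes were lower for 3 of 32 and higher for none (6 and 0 adjusted over the list alone; camera adjusted p = 0.00879, and adjusted p = 0.0918 with an estimated correlation), with ADM at -0.73, PFKFB3 at -0.63 and EGLN1 at -0.61. S phase genes were lower for 3 of 40, ORC1, POLA2 and RFC3 at -0.83, -0.67 and -0.59 (3 and 0 adjusted over the list alone; camera adjusted p = 0.0218, and adjusted p = 0.201 with an estimated correlation). The 12 genes of mitochondrial DNA had a median of 0.77 with 0 calls by limma (0 adjusted over the list alone; camera adjusted p = 0.00152, and adjusted p = 0.626 with an estimated correlation), and ATP6 read 1.22 higher (adjusted p = 0.124). The 44 cytosolic ribosomal proteins had 0 calls and a median of 0.21 (0 adjusted over the list alone; camera adjusted p = 0.0218, and adjusted p = 0.879 with an estimated correlation), with RPS23 at 0.81 (adjusted p = 0.0963). Relative to all genes that median was 0.19, and it turned to -0.033 with normexp, -0.051 with quantile normalization and -0.0083 in the authors' table. The glycolysis call was lost without control replicate 1 (adjusted p = 0.0776) and with median centring (0.0603). S phase lost its call without control replicate 3 (0.154) or ATG5 replicate 2 (0.124), and with median centring (0.105), the replicate block (0.094) or the slide row term (0.124). The ribosomal proteins lost theirs without control replicate 1 (0.121) or 3 (0.45) or ATG5 replicate 2 (0.433). They also lost it with no filter (0.0875), the mean of a gene's probes (0.138), the replicate block (0.135) or the slide row term (0.433). The gene calls were lost without ATG5 replicate 2 (0.166 to 0.235), and all or most of them without ATG5 replicate 1 (0.0619 to 0.0961), control replicate 2 (0.0533 to 0.0794) or 3 (0.064 to 0.104), or NPM1 replicate 1 (0.0749 to 0.117), 2 (0.0858 to 0.108) or 3 (0.0758 to 0.105).

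Other lists held few calls in the ATG5 shRNA arrays and were not called by camera. CCL2, a monocyte chemokine, rose by 1.09 (SE 0.09, adjusted p = 0.00418), the 1 call of the NF-kB list (5 higher adjusted over the list alone; camera adjusted p = 0.395), and IFIT5 rose by 1.08 while DDX60 and USP18 fell by 1.05 and 0.70 among interferon genes (2 higher and 7 lower adjusted over the list alone; 0.429). Cholesterol synthesis held 2 lower genes, TM7SF2 (-1.09) and IDI1 (-0.68) (4 lower; 0.0727), and the ATF4 list VLDLR (-0.86) and DDIT4 (-0.54) (3 lower; 0.772). EDEM1 (-0.68) of the unfolded protein response (1 lower; 0.759), BCL2 (-0.62) of the apoptosis regulators (1 lower and 2 higher; 0.353) and MRTO4 (0.60) of ribosome biogenesis (1 higher; 0.772) were the single calls of their lists. So were TFRC (-0.49) of the erythroid list (1 lower and 1 higher; 0.781) and COL1A2 of the fibroblast list (1 lower; 0.429), while the calls among lymphoid markers were 1 higher, IL7R (1.07), and 1 lower (3 lower and 2 higher; 0.772). No member was called by limma among G2/M genes (camera adjusted p = 0.912), oxidative phosphorylation (0.361), histones (0.361) or immediate early genes (0.817). AURKB, H2BC7 and HSPA8 came closest in the G2/M, histone and immediate early lists at -0.82, 0.46 and -0.57 (adjusted p = 0.0845, 0.142 and 0.0629). MYC differed by -0.26 (adjusted p = 0.347). The median, mean and camera sign differed for G2/M (0.03, 0.01, down), ATF4 (0.06, -0.09, down), immediate early (0.04, -0.05, up), erythroid (0.05, -0.07, down) and fibroblast lists (0.06, -0.06, down). The mean of the ATF4 list includes the gene ATF4 at -3.34, not called by limma (adjusted p = 0.307). That gene read 6.12 on ATG5 replicate 1 and -0.66 on ATG5 replicate 2, where it lay among the dark spots described below. With normexp, cholesterol synthesis (adjusted p = 3.13e-05), histones (3.13e-05), G2/M (0.00143) and 4 further lists were called lower, and oxidative phosphorylation turned from a median of 0.09 relative to all genes to -0.15 (0.0278). Cholesterol synthesis was also called with quantile normalization (0.0248), no filter (0.017) or array weights (0.0289), in the authors' table (0.0206) and without control replicate 2 (0.0457). Histones were also called with array weights (0.0289) and without control replicate 1 (8.38e-05) or ATG5 replicate 1 (0.0364). Without ATG5 replicate 2 all of the gene calls but that of CCL2 were lost (0.0622 to 0.24). Many were also lost without ATG5 replicate 1 (0.0768 to 0.139), control replicate 2 (0.061 to 0.0834) or 3 (0.0684 to 0.108), or NPM1 replicate 1 (0.078 to 0.133), 2 (0.051 to 0.124) or 3 (0.0636 to 0.113).

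The third comparison set NPM1 shRNA against ATG5 shRNA, both with doxycycline. RB1 was at least 307-fold lower with NPM1 shRNA, RCBTB2 at least 148-fold, CD93 at least 128-fold, HOXA6 at least 90.0-fold and CEP15 at least 55.2-fold. MEGF6 was at least 30.0-fold higher and BRINP3 at least 13.4-fold, and the interferon gene IFI27 and DNAI3 were higher by 5.77 (SE 0.71) and 5.65 (SE 0.22). The targets differed as labelled, with NPM1 at -1.95 (SE 0.32, adjusted p = 0.00478) and ATG5 at 1.00 (SE 0.12, adjusted p = 0.00143). limma called 5188 genes, 2290 higher and 2898 lower, and 1994 differed at least 2-fold with dim signals at their bound (615 higher, 1379 lower). DNAI3, IFI27 and MPO were well above background on 1 of 2 ATG5 arrays. IFI27 was 7.19 or 4.36 higher without ATG5 replicate 1 or 2. The groups did not overlap for 66.2% of genes, where chance gives 20%. Of the calls 44.1% were higher, against 33.5% with normexp, 53.5% with quantile normalization, 66.0% with median centring and 54.2% in the authors' table. The median of all genes was -0.13, and -0.29 with normexp and 0.13 with median centring. The count was 2874 without ATG5 replicate 2, where the lone array is again assumed to vary like the other groups, 3195 or 3151 without NPM1 replicate 1 or 2, and 7907 with only these groups in the fit.

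Most members of the HOX list differed between the hairpins. HOXA3 was at least 74.1-fold, HOXA7 at least 48.1-fold and HOXB8 at least 29.5-fold lower with NPM1 shRNA, and HOXA10, HOXA9 and MEIS1 differed by -1.13, -0.58 and -0.60 (adjusted p = 0.00289, 0.00567 and 0.00434). Of 21 measured HOX and MEIS genes 16 were lower and 2 higher (16 and 3 adjusted over the list alone; camera adjusted p = 5.52e-06, and adjusted p = 0.118 with an estimated correlation). CD14 differed by -2.28 (SE 0.10, adjusted p = 1.25e-05), FCN1 by -4.26 and CD163 by -3.88, FCGR3A was at least 4.77-fold lower, and ITGAM differed by 0.45 (adjusted p = 0.0587). Of 25 monocyte genes 11 were lower and 4 higher (12 and 5 adjusted over the list alone; camera adjusted p = 0.0438, and adjusted p = 0.237 with an estimated correlation). MPO was higher by 2.60 (SE 0.37, adjusted p = 0.00265), and CEACAM1 and the gelatinase MMP9 stood at -2.87 and -1.97, among 6 higher and 4 lower of 16 neutrophil genes (6 and 5 adjusted over the list alone; camera adjusted p = 0.541). IL3RA stood at -1.87 and FLT3 at 1.51, among 3 lower and 1 higher of 11 stem and progenitor genes (4 and 1 adjusted over the list alone; camera adjusted p = 0.541). PBX3 differed by -0.50 (adjusted p = 0.0436). MPO was 3.31 or 1.89 higher and HOXB8 at least 47.5-fold or 18.3-fold lower without ATG5 replicate 1 or 2. The HOXA9 and MEIS1 calls were lost with median centring. The PBX3 call was lost without ATG5 replicate 1 (0.129) or 2 (0.168), control replicate 3 (0.0565), or NPM1 replicate 1 (0.112), 2 (0.0965) or 3 (0.129). The monocyte list lost its call without control replicate 1 (adjusted p = 0.0737), 2 (0.119) or 3 (0.0685), ATG5 replicate 1 (0.0621) or NPM1 replicate 3 (0.0558), and in 6 alternatives that left out no array besides the estimated correlation.

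GABARAPL1 differed by -1.84 between NPM1 and ATG5 shRNA (SE 0.10, adjusted p = 2.46e-05), the phosphoinositide binder WIPI1 by -1.10, and ATG3, which conjugates LC3, by 0.77. SQSTM1 and MAP1LC3B differed by 0.31 and 0.36 (adjusted p = 0.0655 and 0.0519). Of 38 autophagy genes 6 were higher and 3 lower (8 and 3 adjusted over the list alone; camera adjusted p = 0.152). Of 40 lysosomal genes 11 were higher and 4 lower (12 and 4 adjusted over the list alone; camera adjusted p = 0.0127, and adjusted p = 0.149 with an estimated correlation), with the channel MCOLN1 at 0.81, FUCA1 at -1.37 and CTSH at -1.32. Glycolysis and hypoxia genes were lower for 13 of 32 and higher for 1 (14 and 1 adjusted over the list alone; camera adjusted p = 0.00337, and adjusted p = 0.118 with an estimated correlation). ADM was at least 10.5-fold lower, and ENO2 and ALDOC stood at -2.02 and -1.95. Oxidative phosphorylation genes were higher for 6 of 38 (6 and 0 adjusted over the list alone; camera adjusted p = 0.00878, and adjusted p = 0.552 with an estimated correlation), with SDHB of complex II at 0.90. Cytosolic ribosomal proteins had 1 call of 44, RPL22 at -0.60 (1 adjusted over the list alone; camera adjusted p = 0.008, and adjusted p = 0.811 with an estimated correlation), and the list call was lost without ATG5 replicate 2 (0.0599), with normexp (0.0896), with quantile normalization (0.741) and in the authors' table (0.515). Erythroid markers were lower for 6 of 19 and higher for 1 (8 and 1 adjusted over the list alone; camera adjusted p = 0.00826, and adjusted p = 0.463 with an estimated correlation), with HBB at -3.97 and PPBP at least 3.38-fold lower.

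The other lists were not called by camera between the hairpins. BIK, BMF and BCL2 were higher by 3.22, 2.05 and 1.98 among 5 higher and 7 lower apoptosis regulators (7 and 9 adjusted over the list alone; camera adjusted p = 0.786). EDA2R was 2.42 higher and SPATA18 at least 2.64-fold lower among 6 higher and 8 lower p53 targets (7 and 10; 0.786). CDKN1A and MYC differed by 0.30 and -0.27 (adjusted p = 0.37 and 0.221). IFI44 and HERC5 were higher by 3.30 and 2.40 among 11 higher and 6 lower interferon genes (13 and 10; 0.0572). CCL2, which recruits monocytes, stood at -1.19 among 5 higher and 9 lower NF-kB genes (5 and 11; 0.368). EBP stood at -2.20 among 1 higher and 8 lower cholesterol genes (1 and 8; 0.0565). The counts were 6 higher and 6 lower for NRF2 targets (6 and 7; 0.786), 8 and 10 for ATF4 (9 and 10; 0.849), 1 and 2 for the unfolded protein response (1 and 0; 0.152) and 0 and 1 for mitochondrial DNA (0 and 0; 0.192). They were 2 and 2 for ribosome biogenesis (0 and 0; 0.786), 2 and 0 for G2/M (0 and 0; 0.428), 6 and 3 for S phase (6 and 3; 0.368), 0 and 2 for histones (0 and 0; 0.0572) and 5 and 4 for immediate early genes (5 and 4; 0.786), where HSPA6 stood at -2.09. Lymphoid markers held 3 and 3 (3 and 3; 0.786), with EBF1 at -3.26, and fibroblast markers 1 and 3 (1 and 3; 0.152), with COL6A1 at -1.64. The median, mean and camera sign differed for ribosome biogenesis (-0.06, -0.00, up), G2/M (-0.03, 0.01, up), NRF2 (-0.08, -0.06, up), apoptosis (-0.17, 0.11, up), immediate early (0.01, -0.11, up) and lymphoid lists (0.06, -0.19, up). Interferon was called higher with normexp (adjusted p = 0.0263), no filter (0.00556), the mean of a gene's probes (0.0348) or the slide row term (0.0218), and without ATG5 replicate 1 (0.0218). Core autophagy was called higher with normexp (0.0237), no filter (0.0133) or the mean of probes (0.0497). Cholesterol was called lower with quantile normalization (0.0264), the mean of probes (0.0348) or array weights (0.0482), in the authors' table (0.0237) and without ATG5 replicate 2 (0.029) or NPM1 replicate 2 (0.0451). Histones were called lower with quantile normalization (0.0161), the replicate block (0.0473), these groups alone (0.00159) or array weights (0.0112) and in the authors' table (0.0104). They were also called without control replicate 1 (0.00977), control replicate 2 (0.0115) or ATG5 replicate 2 (0.00824). With normexp or no filter, S phase (0.00553 and 0.0492) and the unfolded protein response (0.00858 and 0.0135) were called higher. With normexp G2/M (0.00553) and ribosome biogenesis (0.0295) were called higher, and with no filter the fibroblast list (0.0291) was called lower.

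Both comparisons against control used the same control arrays. They shared 367 called genes, of which 185 moved in the same direction, 108 up, such as CAMP, EDA2R and NQO1, and 77 down, such as VLDLR, ADM and COL1A2. Independent lists of these sizes would share 66.7 genes in the same direction. Arrays of all 3 groups simulated as independent noise without any effect shared 0.01 on average and 1 at most. Without an effect almost no gene is called in either comparison, so this count cannot show what the shared controls add to the 185. The fold changes correlated at 0.164 across genes against 0.446 in the simulations, with a covariance of 0.0639 against 0.0348 simulated, a difference of 0.0292. The simulations gave each group the pooled spread, while the median SD of a gene was 0.25 in control, 0.13 in ATG5 and 0.09 in NPM1 arrays. The simulated covariance may therefore be too low for these controls, and the difference cannot be read as a shared change. With 3 control arrays each comparison could not be given 2 of its own, so part of the excess over independent lists may come from the shared controls. The shared count was 0 with only 2 groups per fit, where limma called 0 genes for ATG5 shRNA (2658 at an unadjusted p under 0.05). It was 1434, 84 or 76 without control replicate 1, 2 or 3, 103 or 14 without ATG5 replicate 1 or 2, and 31, 31 or 37 without NPM1 replicate 1, 2 or 3.

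**Figure D4:**
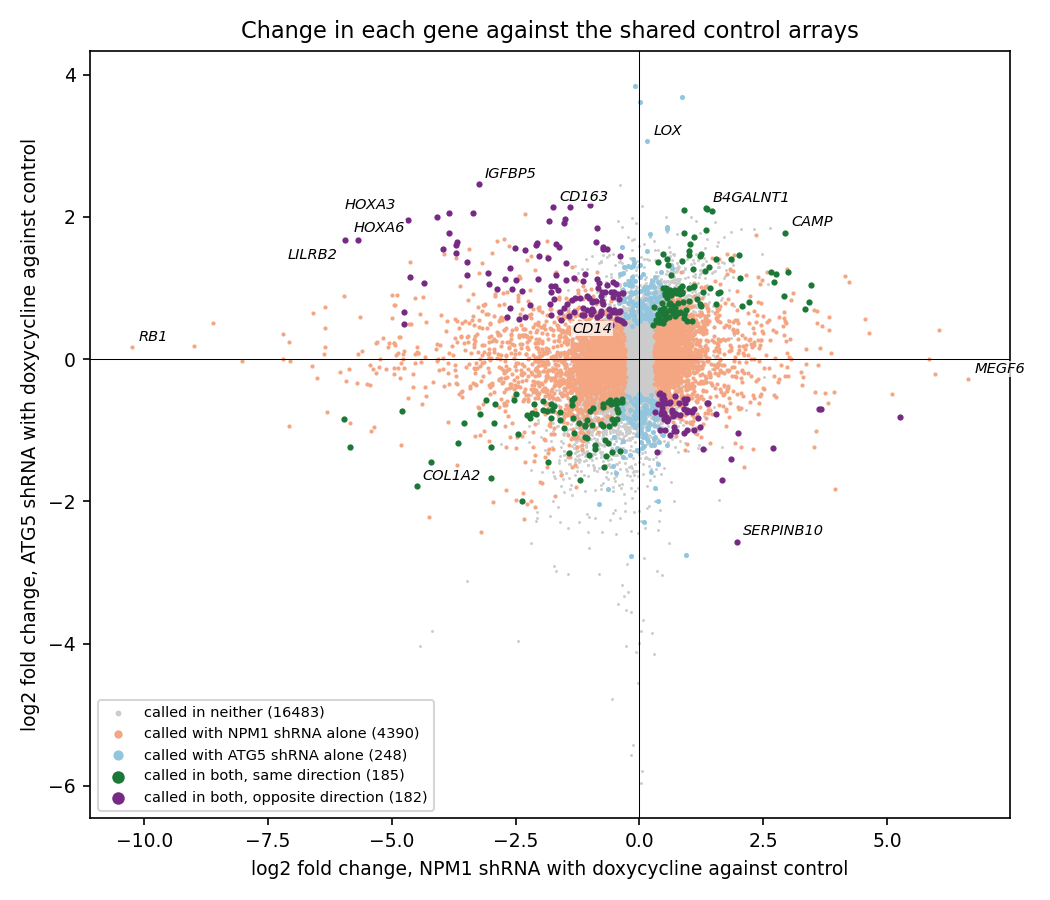
Each point is 1 gene, with the log2 fold change of NPM1 shRNA against control on the x axis and of ATG5 shRNA against control on the y axis, coloured by which comparison called it. Across genes the changes correlated at 0.164. Fitted values are drawn also for genes that have only a bound in a group.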

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

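All tests in this part were chosen after the results were seen, except the counts over other splits of the arrays.

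Against control, 182 genes were called in opposite directions in the NPM1 and ATG5 shRNA arrays. Limma called each of them between the hairpins as well, which adds no support, since opposite changes add up in that comparison. Of these, 121 were lower with NPM1 shRNA and higher with ATG5 shRNA, where independent lists would share 44.5, and 61 went the other way, against 24.99. The count depends on the ATG5 calls. It was 103 or 17 without ATG5 replicate 1 or 2, 92 or 57 without control replicate 2 or 3, and 43, 39 or 56 without NPM1 replicate 1, 2 or 3. Without control replicate 1 there were 461, of which 282 and 179 in each direction stood under the 289.8 and 215.6 of independent lists, so no excess was left. There were 0 with only 2 groups in each fit or with the replicate block, where limma called 0 genes for ATG5 shRNA (2658 and 3440 at an unadjusted p under 0.05), and 10 to 252 in the other alternatives. The 182 included SERPINB10, a serpin of myeloid cells, at 1.96 with NPM1 shRNA and -2.57 with ATG5 shRNA, and CD14, HOXA3 and HOXA6, which were lower with NPM1 and higher with ATG5 shRNA.

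In the HOXA cluster, HOXA3, HOXA5, HOXA6 and HOXA7 were called lower with NPM1 shRNA and higher with ATG5 shRNA. HOXA2 and HOXA4 were lower with NPM1 shRNA and not called with ATG5 shRNA, where they differed by 1.35 and 1.67 (adjusted p = 0.0989 and 0.0683). Of HOXA2 to HOXA7, HOXA5 alone was well above background on any NPM1 array (1 of 3), so signals under the lowest one well above background on an array were raised to it. Their median was then -3.75 in NPM1 shRNA and 1.61 in ATG5 shRNA arrays against control. Array scaling was excluded as the whole cause, since both directions held in each pair of a hairpin and a control array under 5 scalings. The ATG5 side was weakest with no scaling, at 0.87 (pairs from 0.25 to 1.54), where all genes had a median of -0.72. The spread of the control arrays stays open for the ATG5 side. The largest difference of this median between control arrays was 0.22, 0.30, 0.38 and 0.56 with the 4 ways of scaling, under the weakest ATG5 pair (1.62, 1.67, 1.62 and 1.51). With no scaling it was 0.91, over the weakest ATG5 pair at 0.25. The NPM1 side was beyond it in each case, with weakest pairs from -3.29 to -2.90. For single genes the ATG5 calls depend on the fit: with only ATG5 and control arrays in it, HOXA3, HOXA5, HOXA6 and HOXA7 were not called. Clones or cell populations that differ between the groups were not tested, and a biological difference stays open as an untested hypothesis.

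In the NPM1 shRNA arrays 65 genes differed at least 16-fold from control with dim signals raised in the same way, among them RB1, RCBTB2 and CD93, and 116 did by fitted values. As a set, these 65 genes moved little in the ATG5 shRNA arrays, which also received doxycycline. Signed by the NPM1 change, their median there was -0.065 (quartiles -0.50 and 0.20), against 4.75 in the NPM1 arrays. This argues against a doxycycline effect of like size in both hairpin groups as the cause for the set. A doxycycline effect on the cells of the NPM1 group alone stays open, since no array of that group lacked it. All 65 were called in the same direction between the hairpins. This adds no support, since they were picked by a large change in the same NPM1 arrays. In ATG5 shRNA against control 3 were called in the same and 7 in the opposite direction. Gain or loss of chromosome segments that span most of the 10 nearest tested genes was excluded for the set. Those genes had a median signed change of 0.13 (quartiles 0.010 and 0.30). The test covers the 57 genes with a usable position. For 9 of them the nearest genes moved by over 0.5 in the same direction, so such a segment stays open there. A segment of a few genes would not show in this median and stays open for all of them. RB1 and its neighbour RCBTB2, for example, were at least 272-fold and 130-fold lower. Cells of a separately derived population in the NPM1 group could not be excluded. Of the called genes, 179 were well above background on all 5 other arrays and on no NPM1 array. For the ATG5 arrays this count was 14. Against control, limma called 2692 genes lower for NPM1 shRNA and 260 for ATG5 shRNA, so the 179 and 14 cannot be compared as they stand. A separate population cannot be told apart from an effect of the hairpin because each hairpin has its own group. Of the 10 splits of the control and NPM1 arrays 1, the real one, called as many genes (4757, highest other 0 by limma with 140 to 1104 genes at an unadjusted p under 0.05) and as many lists (8, against 3 to 6 in every other split), and 10 splits are too few for a share under 0.05. Camera at the preset correlation thus called lists also in splits that mix the groups, where limma called 0 genes.

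The 185 genes called in the same direction in both comparisons might come from either of 2 shared conditions. The control arrays enter both comparisons, and 3 of them cannot be divided into groups of 2, so their part in the 185 cannot be told apart from a shared change. Doxycycline was in both hairpin groups and not in the control, and with 0 hairpin arrays without doxycycline its part cannot be told apart either. An effect common to both hairpins stays open and untested.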

How the results depend on the processing

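The term for the slide row was chosen after the data were seen, as was the look at HOXA genes without scaling. Over all alternatives, lists stayed on the same side of the threshold in 1443 cases. They gained a call in 61, lost it in 52 and turned in 4. For named genes the counts were 4777, 41, 935 and 4. Direction was compared only where a result was called in at least 1 of the fits, and not with the estimated correlation. Results called in neither fit count as kept whatever their direction. Glycolysis and lysosome in NPM1 shRNA against control kept their calls in each of 20 alternatives. The alternatives other than the estimated correlation all used the preset correlation, which also called lists in splits that mix the groups. With normexp 3040 genes were called for NPM1 shRNA against control, 252 for ATG5 shRNA and 56 in both with the same sign, GARIN1A, KSR1 and MATN2 turned to 0.16, 0.36 and 0.29 with ATG5 shRNA, LCK turned to -0.21 between the hairpins, and relative to all genes ribosomal proteins turned to -0.033 and oxidative phosphorylation to -0.15. LCK and the other turned genes were near background in 1 group. Ribosomal proteins also turned to -0.051 with quantile normalization and to -0.0083 in the authors' table. Median centring gave 173 ATG5 calls and 55 in both, no filter on dim probes 91 and 25, an adjusted p under 0.01 gave 25 in both, a variance trend with robust estimation 1005 and an ATG5 level of -0.59 that was called, and array weights 366. The slide row term gave 1525, 44 and 11, and an NPM1 level of -2.25. The cause of these shifts was not tested.

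With only the 2 groups compared, limma called 0 genes for ATG5 shRNA (2658 at an unadjusted p under 0.05), 7907 between the hairpins and 0 in both. Fewer arrays then set the spread, and the groups differ in it. The median SD of a gene was 0.25 in control, 0.13 in ATG5 and 0.09 in NPM1 arrays. The spread pooled over all groups may therefore be too small for ATG5 shRNA against control and too large between the hairpins. With the replicate number as a block it called 0 for ATG5 shRNA (3440 at an unadjusted p under 0.05), 3026 between the hairpins and 0 in both. Same-numbered arrays did not deviate together (r from -0.16 to 0.16), so this check found no pairing by number. It cannot exclude one, since deviations from the mean of 2 or 3 arrays are not independent.

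Leaving out 1 array gave 2861 to 6676 genes for NPM1 shRNA, 44 to 3239 for ATG5 shRNA, 2874 to 6521 between the hairpins and 14 to 1434 in both, an NPM1 level from -1.74 to -1.27 and an ATG5 level from -0.69 to -0.50. The highest counts came without control replicate 1 and the lowest for ATG5 without ATG5 replicate 2, where the lone array is assumed to vary like the other groups. The slide as a block was not run, since all arrays shared 1 slide. Dim probes limit what can be seen on ATG5 replicate 2, where the 75th percentile stood 19.8 times above background, against 50.5 on control replicate 3.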

Other observations

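The searches in this part were chosen after the data were seen, and each is given as values only.

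Among the 35 genes that kept their ATG5 shRNA call whichever array was left out, some outside the rule for names were picked after their values were seen. TREM1, an amplifier of myeloid inflammation, rose by 1.54 (SE 0.13, adjusted p = 0.00453), LILRB2 by 1.67, SIGLEC14 by 1.35 and the integrin ITGB7 by 1.41, and the cobalamin carrier TCN1 differed by -1.30. They were not tested as a group. With only the ATG5 and control arrays in the fit limma called 0 genes (2658 at an unadjusted p under 0.05).

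Around RB1 on chromosome 13, of the genes within 500 kb, LPAR6, a receptor gene that lies inside RB1, was at least 3.64-fold higher in the NPM1 shRNA arrays (adjusted p = 3.28e-05), while RCBTB2 was at least 130-fold lower. MED4 and ITM2B differed by -0.21 and -0.27 and were not called (adjusted p = 0.215 and 0.144).

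Along the genome, adjacent genes had correlated changes in each comparison. The rank correlation across genes was 0.118 for NPM1 shRNA against control, where 200 shuffles reached 0.0272 at most, 0.0435 for ATG5 shRNA against control (0.0282) and 0.0904 between the hairpins (0.0298). Genes are not independent replicates here.

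On ATG5 replicate 2, 94 spots of 77 genes were at least 8-fold under the lowest of the other 7 arrays, with a median distance of 1.41 spots to the nearest such spot against 12.3 for random spots. Control replicate 2 had 37 such spots of 29 genes, at 2.24 against 20.2, control replicate 1 had 1, and the other arrays 0. ATF4 was among them, at -0.66 on ATG5 replicate 2. Of these genes on ATG5 replicate 2, 1 was called for ATG5 shRNA against control and 10 between the hairpins. Probes for ERCC control transcripts were well above background for 8.57% to 10.3% of spots on control arrays and 5.54% to 6.37% on hairpin arrays.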
